A study of Citrus trifoliata with 2 samples.

How the data were processed

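RNA sequencing was carried out on buds of trifoliate orange (Citrus trifoliata), a deciduous citrus relative used as a rootstock. According to the labels, 1 library came from an early-flowering mutant and 1 from its wild type. The buds were taken from young trees at flower initiation, after the shoot tip had been shed, and the RNA was selected for poly(A) tails. The groups were taken from the source names in the labels, and each group holds 1 library.

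The deposited table lists 35775 unigenes, which are transcript models with no genome position. Per the file headers, it gives the raw read count of each unigene in each library, and the header also states the library totals. Those totals were 10037091 reads for the mutant library and 9995030 for the wild-type library, and they equalled the column sums. Per the file headers, the authors also deposited RPKM values, that is, reads scaled to the length of the unigene in kilobases and to the library total. The RPKM values were recomputed from the counts, lengths and totals, and 100% of them matched within 1e-04 in both libraries. Unigene length in bases is deposited as a further column and is of another kind (other); it ranged from 200 to 8253, with a median of 547. The assembler, the aligner, the counting tool, the filters and the strand setting are not given in the sources used here. It is therefore not known how reads shared between near-identical copies were counted, so members of large gene families are uncertain. Several unigenes can be pieces of 1 transcript, so numbers of unigenes are not numbers of genes.

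Names were taken from the Swiss-Prot best hits in the same table, which covered 18809 unigenes (52.6%) at E-values of at most 1e-05. A best hit names the closest listed protein and can come from another species. The hits to the larger protein collection in the table were drawn mostly from species other than plants and were not used.

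The main value was log2((mutant RPKM + 1) / (wild-type RPKM + 1)). A unigene was kept when its RPKM was at least 1 in at least 1 library, which left 34255 unigenes and set aside 1520. A unigene was counted as higher or lower when this ratio reached 2-fold, a log2 ratio of 1. The pseudocount understates the difference of unigenes with few reads. With 1 library per group no test across trees was possible, and no count-based model was fitted. Folds of named unigenes were computed from the raw counts and library totals, with an exact 95% binomial (Clopper-Pearson) interval. Where a library had 0 reads, the fold was computed against a floor of 3 reads and is given as "at least". This bound takes the reads of the other library as exact, and the lower limit of the exact interval is smaller in each case.

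Before the data were examined, 28 gene lists were fixed by words in the annotation or by Arabidopsis locus codes. The median log2 ratio of each list was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. The percentile describes these libraries and is no test of the genotypes. Where a 95% interval of a list median is given, it comes from the order statistics of the members and covers their spread, not differences between trees. A second percentile, added after the data were seen, also matched the block of unigene numbers described with the results. In the lists, 6 accidental word matches were removed after they had been seen. The list of fungal genera used to sort best hits was likewise written after fungal hits had been seen.

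The named unigenes followed a rule fixed in advance. It takes the 10 largest positive and 10 largest negative log2 ratios with an annotation naming a gene or function. It takes up to 4 members with the largest absolute ratio from the lists for floral promoters, floral repressors, floral organ identity, photoperiod and clock, gibberellin and meristem, and up to 2 from every other list. It adds FT, SOC1, LFY, AP1, TFL1, FLC and SVP whatever their ratio. The rule gave 86 unigenes, of which 17 had an E-value above 1e-10. Names outside this rule are marked as such.

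Blocks of unigene numbers were found from unigene length alone, with a window of 200 unigenes. Along the numbering, runs of unigenes sorted by length end in an abrupt drop of length at several places. The method was revised after its first results had been seen, since its first form missed a boundary. The boundaries were then moved to the largest drop in length nearby.

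The alternatives fixed in advance were other pseudocounts (0.1 and 5), no minimum, a minimum RPKM of 5, centring on the median ratio, scaling by a trimmed mean of the ratios (30% trimmed on the ratio and 5% on the level), a 4-fold threshold and a counting interval that excludes 1. Added after the data were seen were restriction to the first 2 number blocks, to at least 100 reads, to at least 500 bases, to unigenes without a fungal best hit and to the longest unigene per Swiss-Prot entry, and keeping the accidental word matches.

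The steps were tested on simulated data for the mutant against wild-type comparison. Poisson reads were drawn for 35775 unigenes. Of these, 200 differed 4-fold, all picked from kept unigenes with at least 100 reads, so recovery of sparsely read changes was not tested. The 2-fold rule found 100% of the raised and 100% of the lowered ones. It also counted 456 unchanged unigenes as higher and 452 as lower, but 1 and 0 among those with at least 100 reads. Among unigenes with at least 100 reads, the counting interval covered the true fold for 95.5%, and coverage below that depth was not measured. Of 1000 random lists without a difference, 63 (6.30%) fell outside the middle 95%. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.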

Results

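The transcriptome of buds was compared between the precocious mutant of trifoliate orange, which flowers early, and its wild type, with 1 library of each and no replicates. In units of 1000 reads, the mutant library held 10037 on unigenes and the wild-type library 9995. At least 1 read was found for 35155 unigenes in the mutant library and 35106 in the wild-type library. Across the 34255 unigenes kept, log2 levels of the libraries had a Pearson correlation of 0.94 and a Spearman correlation of 0.89; unigenes are not independent replicates. The 10 most abundant unigenes took 1.04% of the mutant reads and 1.06% of the wild-type reads. Intervals given after folds are exact 95% intervals that cover counting error only, not differences between trees.

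The comparison asked which transcripts differ in buds of the early-flowering mutant at the time of flower initiation. Several floral promoters were higher in the mutant library. FLOWERING LOCUS T (FT), the mobile flowering signal, was 3.57-fold higher (1.85 to 7.43, Unigene27861, 43 reads against 12). The unigene closest to potato AGL8, a relative of FRUITFULL that acts in the inflorescence meristem, was 3.23-fold higher (2.53 to 4.17, Unigene12163, 276 reads against 85). APETALA 1 (AP1), which specifies floral meristems, had 12 reads in the mutant library and 0 in the wild-type library, at least 3.98-fold higher against the floor of 3 reads, with an exact lower limit of 2.77 (Unigene27120). SOC1, a MADS-box integrator of flowering signals, matched 4 unigenes. Unigene3347 was 2.74-fold higher (1.17 to 7.11, 22 reads against 8), and the intervals of Unigene1570 (8 against 6), Unigene19004 (6 against 3) and Unigene19612 (4 against 5) included 1.

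Of the 12 kept floral promoters, 4 were at least 2-fold higher, 0 were at least 2-fold lower and 11 had a positive ratio. Their median log2 ratio was 0.30, which became 0.090 over the 5 with at least 100 reads, 0.18 with a pseudocount of 5 and 0.73 over 8 with the longest unigene per entry. That median lay at percentile 85.5 of random lists matched on level, and at 58.4 when the number block was matched too, so the list as a whole did not stand apart. Protein FD, the partner of FT, was at 81 against 79 reads (1.02-fold, 0.740 to 1.41, named after its values were seen). SPL4 was at 162 against 161 reads and was likewise named afterwards.

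**Figure D1:**
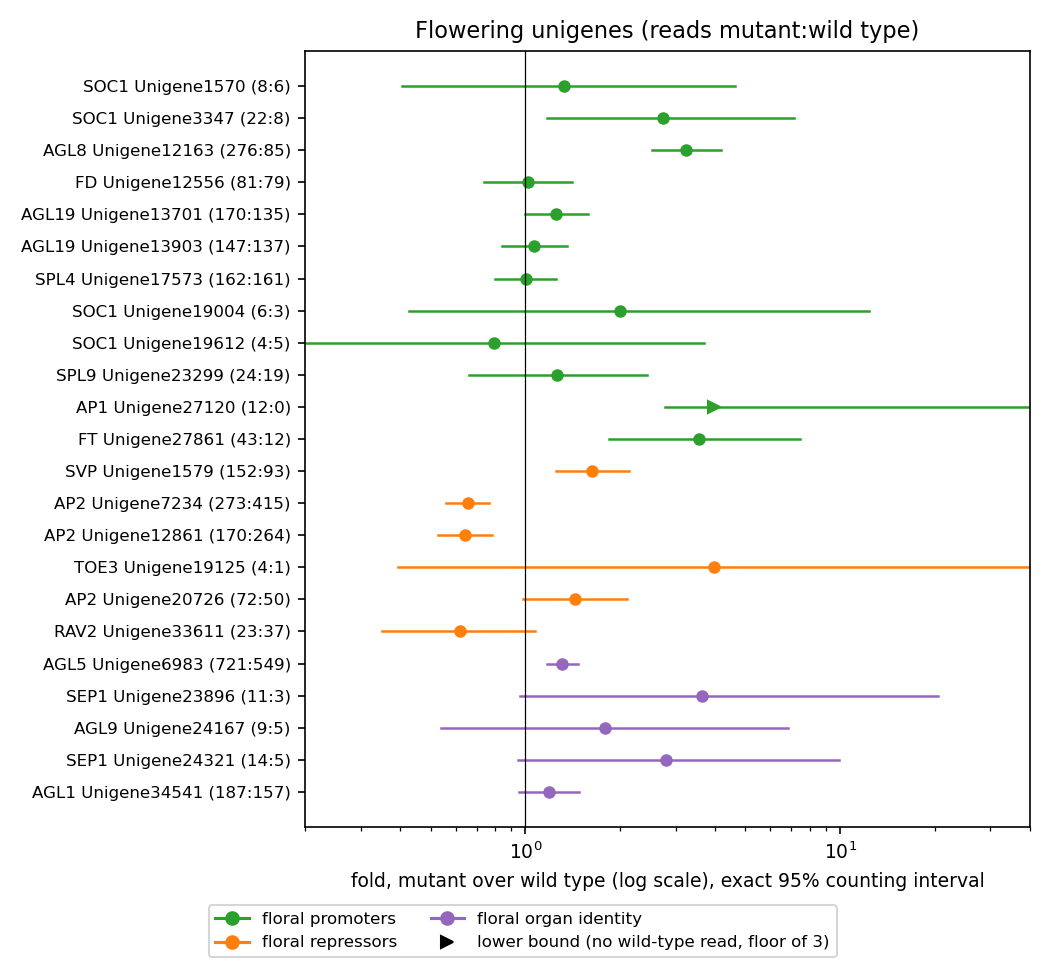
Fold of each kept unigene of the floral promoter, repressor and organ identity lists, mutant over wild type on a log axis, with exact 95% counting intervals and reads per library in brackets. The triangle marks AP1 (12 against 0 reads), drawn at 3.98 against a floor of 3 reads with the exact lower limit at 2.77; FT and AGL8 lie above 3.

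Floral repressors went both ways. SVP, a MADS-box repressor of flowering, was 1.63-fold higher in the mutant library (1.25 to 2.13, Unigene1579, 152 reads against 93). APETALA 2, which also restrains flowering in Arabidopsis, was 1.56-fold lower (1.28 to 1.90, Unigene12861, 170 against 264) and 1.53-fold lower (1.31 to 1.79, Unigene7234, 273 against 415). The longest of the APETALA 2 hits, Unigene20726, leaned the other way at 1.43-fold higher (0.986 to 2.10, 72 against 50, named after its values were seen). TOE3 had 4 reads against 1, a ratio of 3.98 (0.394 to 196). None of the 6 kept repressors reached 2-fold in either direction. The median log2 ratio of −0.03 lay at percentile 33.0, and at 14.6 with the number block matched. That median was −0.60 over the 3 in the first 2 blocks, −0.46 over the 5 with at least 500 bases, and 0.52 over 4 with the longest unigene per entry. The annotation gave no kept best hit for LFY, TFL1 or FLC, which were therefore not analysed here.

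Among floral organ identity unigenes, the best hits to SEPALLATA 1 were 3.65-fold higher (0.965 to 20.4, Unigene23896, 11 against 3) and 2.79-fold higher (0.949 to 9.89, Unigene24321, 14 against 5), with intervals that included 1. AGL9, a SEPALLATA relative, had 9 reads against 5 (1.79-fold, 0.539 to 6.81). AGL5, a carpel and fruit MADS-box gene in Arabidopsis, was 1.31-fold higher (1.17 to 1.46, Unigene6983, 721 against 549). All 5 members had positive ratios, and 2 reached 2-fold. The median of 0.56 lay at percentile 96.6, and at 74.5 with the block matched. This list had lost 5 accidental matches, phospholipases, after they were seen, and with them kept its median was 0.28 over 10. Only 2 members had at least 100 reads, with a median of 0.31.

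The photoperiod and clock list had a median of −0.12 over 47 unigenes (95% interval of the median −0.22 to 0.11), at percentile 0.640. Of these, 2 were 2-fold higher and 2 were 2-fold lower. CONSTANS-LIKE 1 was 3.87-fold higher (1.82 to 9.16, 35 reads against 9) and CONSTANS-LIKE 14 was 3.49-fold higher (1.36 to 10.6, 21 against 6), both from weak hits. Cryptochrome DASH was 2.41-fold lower (1.73 to 3.40, 52 against 125). A unigene whose best hit was cryptochrome-1 of a bird (Sylvia borin), not of a plant, had 1 read against 6 (6.03-fold lower, 0.731 to 277).

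The meristem list had a median of −0.11 over 55 unigenes, at percentile 0.960, although its mean of 0.04 had the opposite sign and its median was −0.0044 among unigenes of at least 500 bases. CUP-SHAPED COTYLEDON 2, a boundary gene, was 3.68-fold lower (1.45 to 11.1, 6 reads against 22). Among short pieces matching CLAVATA1, a receptor kinase that limits the stem cell pool, Unigene23543 had 14 reads against 0 and was at least 4.65-fold higher. Unigene32269 (2 against 7) and Unigene28699 (1 against 5) leaned the other way, with intervals that included 1. The autonomous and chromatin list had a median of 0.02 over 41 unigenes at percentile 37.1, which became −0.029 after centring. In it, FLD, a histone demethylase homolog of the autonomous pathway, was 2.69-fold higher (1.52 to 5.01, 46 against 17), and a VRN1 hit was 12.1-fold lower (1.78 to 515, 1 against 12).

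Hormone lists differed from each other. The jasmonate list had a median of 0.42 over 41 unigenes at percentile 100, with 9 at least 2-fold higher in the mutant library, 1 lower and 34 positive. Lipoxygenases carried most of it, with 8 of the 9 and a median of 0.96 over 18 unigenes, whereas 14 TIFY proteins, repressors of jasmonate responses, had a median of 0.20 with 0 past 2-fold in either direction. In the first 2 number blocks the median of the jasmonate list was 0.28. LOX2, a chloroplast lipoxygenase that starts jasmonate synthesis, was 4.90-fold higher (3.17 to 7.86, 123 reads against 25), and a unigene closest to barley LOX2.3 had 14 reads against 1 (13.9-fold, 2.12 to 589). Cytokinin genes had a median of −0.06 over 108 unigenes at percentile 0.630, with 10 at least 2-fold higher and 5 lower. Their median was −0.13 in the first 2 number blocks and −0.11 after centring. Kept unigenes named cytokinin O-glucosyltransferase numbered 39 (median −0.06, 1 at least 2-fold higher and 2 lower). Those named cytokinin N-glucosyltransferase numbered 25 (median 0.03, 7 higher and 1 lower), and both groupings were chosen afterwards. The median of the cytokinin list therefore does not describe cytokinin signalling alone. The response regulator ARR9 had 10 reads against 1 (9.96-fold, 1.42 to 432), and a cytokinin N-glucosyltransferase hit had 0 against 9, at least 3.01-fold lower.

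Gibberellin, auxin, ethylene and abscisic acid lists lay inside the range of random lists. Gibberellin had a median of 0.02 over 71 unigenes (percentile 31.4, 3 higher, 6 lower), with its sign turned by centring (−0.03). A gibberellin 2-oxidase, which inactivates gibberellin, was 4.98-fold higher (1.41 to 26.8, 15 reads against 3), and another had 2 against 9. The gibberellin receptor hit GID1L3 was 15.1-fold lower (2.32 to 634, 1 against 15), and GID1L2 was 3.58-fold higher (1.28 to 12.4, 18 against 5). Auxin had a median of −0.0015 over 159 unigenes (percentile 17.6, 18 higher, 9 lower), with the small auxin-induced 10A5 hit 7.40-fold higher (3.35 to 19.3) and the 6B hit 7.03-fold lower (2.74 to 23.0). Ethylene had a median of −0.0036 over 123 unigenes (percentile 17.6, 8 higher, 8 lower), and AIL6, an AINTEGUMENTA-like factor matched by its name, was 5.31-fold higher (1.52 to 28.4). ETO1, which restrains ethylene synthesis, had 8 reads against 0, at least 2.66-fold higher. Abscisic acid had a median of 0.12 over 23 unigenes (percentile 74.3, 3 higher, 2 lower), and its catabolic enzyme CYP707A3 matched unigenes with 6 against 1 and 10 against 2 reads.

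Cell division genes were higher in the mutant library. Of 156 cell cycle unigenes, 49 were at least 2-fold higher and 6 were 2-fold lower, and the median of 0.37 lay at percentile 100. Histone H3.2 was 10.5-fold higher (6.44 to 18, 189 reads against 18), and histone H2AX was 8.08-fold higher (5.36 to 12.7, 211 against 26). Within the list, 10 of 25 cyclins, 11 of 18 MCM replication helicase unigenes and 15 of 58 kinesins were 2-fold higher, with medians of 0.70, 1.12 and 0.31. The 45 histones had a median of 0.21, with 9 at least 2-fold higher and 1 lower. Reads summed over the 40 unigenes of the histone family, a grouping chosen afterwards, were 18690 in the mutant library against 18911. The summed histone reads were therefore not higher in the mutant library. In the first 2 number blocks the median of the cell cycle list was 0.19, with 9 unigenes 2-fold higher and 0 lower. Over its 62 members with at least 100 reads the median was 0.15, with 10 higher and 0 lower.

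Cell wall and cuticle genes were also higher. Primary wall genes, which loosen or remodel growing walls, had a median of 0.57 over 108 unigenes at percentile 100, with 38 higher and 3 lower. XTH8, a xyloglucan-remodelling enzyme, was 7.80-fold higher (3.33 to 22.3, 47 against 6), and the polygalacturonase subunit JP630 had 16 reads against 0, at least 5.31-fold higher. All 22 xyloglucan enzymes together had a median of 1.13, and 13 were 2-fold higher and 0 lower. The 22 expansin unigenes were less uniform, with a median of 0.55, 5 at least 2-fold higher and 3 lower. Cuticle genes had a median of 0.51 over 87 unigenes (percentile 100, 23 higher, 2 lower), among them a lipid-transfer protein at 4.32-fold (2.82 to 6.82, 117 against 27) and KCS19, of very-long-chain fatty acid synthesis, with 13 reads against 0, at least 4.32-fold. In the first 2 number blocks the cuticle median was 0.30, with 8 higher and 0 lower. The secondary wall list had a median of 0.38 over 35 unigenes (percentile 99.4, 6 higher, 4 lower), yet its named members were lower: xylem cysteine proteinase XCP1 by 8.28-fold (2.95 to 32.2, 4 against 33) and XSP1 by at least 2.68-fold (0 against 8).

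**Figure D2:**
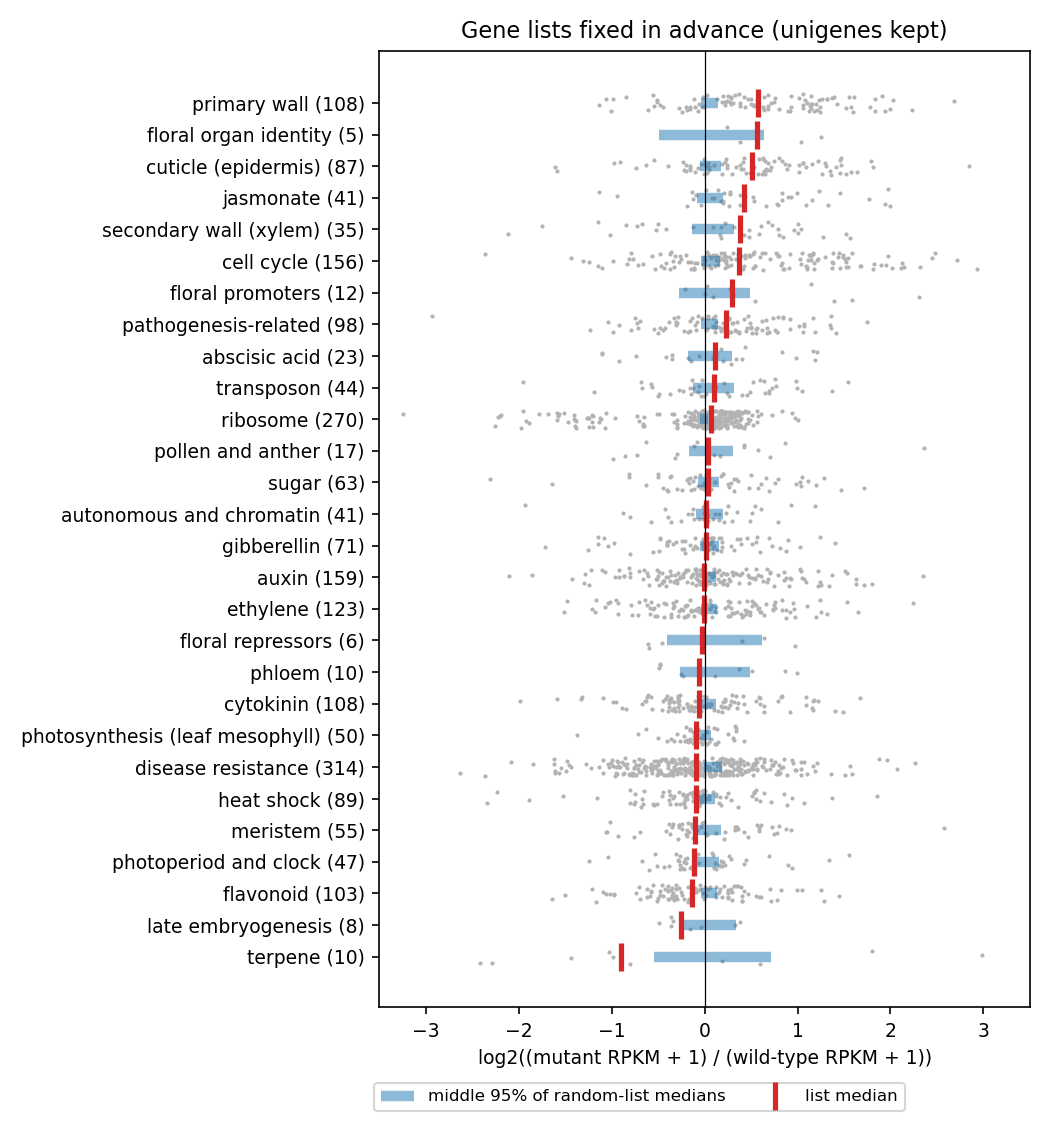
Log2 ratio of RPKM + 1, mutant over wild type, for each kept unigene (grey) of the 28 gene lists, with list medians (red) and the middle 95% of medians of random lists matched on level (blue); the number of unigenes is in brackets. Primary wall (0.57), cuticle (0.51), jasmonate (0.42) and cell cycle (0.37) lie to the right of their random lists, and terpene (−0.90) lies to the left.

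Ribosomal protein unigenes split by the species of their best hit. The 210 with a plant hit had a median of 0.13, and 1 was 2-fold higher and 1 lower. The 50 with a fungal hit had a median of −1.20, and 31 of them were 2-fold lower in the mutant library. The 10 with any other hit had a median of −0.34, and 4 were 2-fold lower. Over all 270 the median was 0.07 (percentile 100) while the mean was −0.11, of the opposite sign. The ribosomal protein L41 unigenes were among the lowest: the yeast hit had 0 reads against 27, at least 9.04-fold lower, and the cork oak hit had 9 against 58 (6.47-fold lower, 3.18 to 14.9).

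Defence lists differed from each other. Pathogenesis-related genes had a median of 0.23 over 98 unigenes (percentile 99.97, 11 higher, 3 lower), with a thaumatin-like protein at 3.98-fold higher (2.47 to 6.68, 88 against 22) and PR-4B at 12.7-fold lower (4.04 to 64.4, 3 against 38). Disease resistance genes had a median of −0.09 over 314 unigenes (percentile 0), with 16 higher and 23 lower; an At1g12290 hit had 0 reads against 13, at least 4.35-fold lower, and RGA3 had 0 against 12. Heat shock genes had a median of −0.10 over 89 unigenes (percentile 0.380), with 3 at least 2-fold higher and 5 lower. The 17 unigenes of heat shock cognate 70 kDa proteins had a median of 0.049, with 3 higher and 0 lower (chosen after their values were seen). The 2 list members with the largest absolute ratios, hits to small class I heat shock proteins, were 9.37-fold lower (2.90 to 48.2, 3 against 28) and 9.54-fold lower (2.30 to 84.5, 2 against 19). Small class I heat shock proteins were not counted as a group.

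The flavonoid list had a median of −0.13 over 103 unigenes at percentile 0, with 4 at least 2-fold higher and 7 lower in the mutant library. The 95% interval of that median (−0.27 to 0.009) included 0, and with the longest unigene per entry the median was −0.0059 over 41. Chalcone synthase 1, the entry enzyme of the pathway, was 3.35-fold lower (2.43 to 4.70, 50 reads against 167), and naringenin 3-dioxygenase was 3.39-fold lower (2.42 to 4.84, 45 against 152). Terpene synthases had a median of −0.90 over 10 unigenes (percentile 0.0900), with 2 higher and 4 lower. The 95% interval of this median (−2.29 to 1.80) included 0, and its sign turned with the longest unigene per entry (0.19 over 3) and for the 1 unigene with at least 100 reads (2.98). Unigenes with the same myrcene synthase hit lay on both sides: Unigene23535 was 18.8-fold higher (10.3 to 38.3, 208 against 11), while Unigene33036 had 0 reads against 33, at least 11-fold lower. With unread unigenes set to the floor, the terpene median shifted by 0.28, the most of any list.

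Photosynthesis genes, markers of leaf mesophyll, had a median of −0.09 over 50 unigenes at percentile 2.16, and at 3.01 with the block matched. PSBQ1 was 3.16-fold lower (1.91 to 5.43, 21 reads against 66) and PSBY 1.92-fold lower (1.14 to 3.33), and of the list 0 were 2-fold higher and 1 lower. Late embryogenesis genes had a median of −0.25 over 8 unigenes (percentile 1.94), with oleosins at 54 against 78 and 6 against 4 reads. The phloem list had a median of −0.06 over 10 unigenes (percentile 21.5), and PP2A1, a phloem lectin, was 1.85-fold higher (1.59 to 2.16, 483 against 260), while PP2A10 had 8 reads against 3. Pollen and anther genes had a median of 0.04 over 17 unigenes (percentile 46.8, −0.01 after centring), and SF3, named pollen-specific in sunflower, was 6.54-fold higher (4.38 to 10.1, 184 against 28), whereas RPG1, needed for pollen wall formation, was 2.51-fold lower (1.32 to 5.05, 14 against 35). Sugar genes had a median of 0.04 over 63 unigenes (percentile 53.1, −0.01 after centring), with 8 higher and 2 lower, and unigenes matching the transporter ERD6-like 5 had 0 reads against 8 and 6 against 0. Transposon genes had a median of 0.10 over 44 (percentile 53.2), with 3 higher and 2 lower. An AC9 transposase hit was 3.77-fold higher (2.53 to 5.75), and a TNT 1-94 retrotransposon hit had 0 reads against 7, at least 2.34-fold lower. The means of the gibberellin (−0.017), auxin (0.073), ethylene (0.064), phloem (0.091) and floral repressor (0.056) lists had the opposite sign to their medians. Altogether 7 of the 28 lists lay above the middle 95% of their random lists and 9 below it.

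The largest single difference toward the mutant library was AHP4, of the phosphotransfer family that relays cytokinin signals, with 637 reads against 2 (317-fold, 87.4 to 2625, Unigene27895). AHP4 was not a member of the cytokinin list. The ribonucleotide reductase chain TSO2, which supplies DNA precursors, had 89 reads against 2 (44.3-fold, 11.9 to 372). An extensin, a wall glycoprotein, had 143 against 5 (28.5-fold, 11.9 to 89.1), and the cytokinesis syntaxin KNOLLE had 101 against 6 (16.8-fold, 7.44 to 46.8). An alpha tubulin was 11.3-fold higher (7.37 to 18.1, 261 against 23). CSLD5, a cellulose synthase-like protein, had 18 reads against 0, at least 5.97-fold higher. Unigene23803 had 154 reads against 0, at least 51.1-fold higher, but its annotation, a kelch protein of human, rests on an E-value of 9e-06.

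Toward the wild-type library, 3 unigenes matching the mRNA-decapping protein DCP1 had 0 reads in the mutant library against 58, 46 and 77, at least 19.4-fold, 15.4-fold and 25.8-fold lower. A unigene matching SMC3 of fission yeast, a cohesin subunit, had 6 reads against 648 (108-fold lower, 49.6 to 297). The 13 unigenes of that protein family (SMC), grouped afterwards, had a median of 0.51, with 5 at least 2-fold higher and 1 lower. A unigene matching importin alpha-1 had 0 reads against 26, at least 8.70-fold lower. The 12 importin alpha unigenes, grouped afterwards, had a median of −0.07 (0 higher, 2 lower) and 6757 reads against 6902. An apple allergen homolog had 0 against 30, at least 10.0-fold lower. An E3 ubiquitin ligase hit also had 0 against 30. An aldehyde dehydrogenase hit to the mould Alternaria had 0 against 14, at least 4.69-fold lower.

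In total, 2948 unigenes (8.61%) were at least 2-fold higher in the mutant library, 1818 (5.31%) were at least 2-fold lower and 29489 (86.1%) were within 2-fold. The median log2 ratio was 0.05. Unigenes past 2-fold were sparsely read, with a median of 19 reads over both libraries for the higher ones and 16 for the lower ones, against 87 for all kept. With at least 100 reads, 306 were higher and 85 lower. The 2-fold unigenes also followed the unigene numbers. In block 3 (18204 to 28013), 2556 were higher and 26 lower with a median of 0.66, and in block 4 (28014 to 36523), 60 were higher and 1693 lower with a median of −0.55. Blocks 1 and 2 had medians of 0.06 and −0.01, and together held 332 higher and 99 lower among 18198 unigenes. Of the numbers up to 36523, 748 carry no unigene in the table used here, none of them before block 3, for a reason not given in the sources used here. The 10 largest named differences toward the mutant library, AHP4, TSO2, the extensin, KNOLLE and histone H3.2 among them, all lie in block 3, and the 10 largest toward the wild-type library, among them the DCP1, SMC3 and importin hits, all lie in block 4. FT, AP1 and both SEPALLATA 1 unigenes lie in block 3, whereas AGL8 lies in block 2 and SVP, LOX2, H2AX and SOC1 Unigene3347 lie in block 1.

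**Figure D3:**
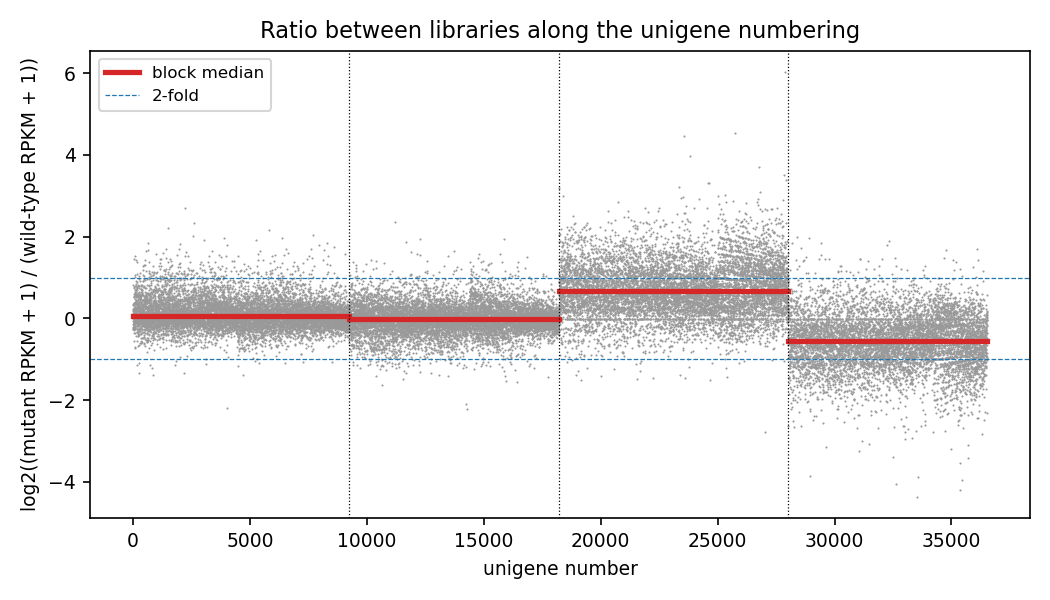
Log2 ratio of RPKM + 1, mutant over wild type, of each kept unigene against its number in the table; dotted lines part 4 blocks found from unigene length, red bars are block medians and dashed lines mark 2-fold. The medians are 0.06, −0.01, 0.66 and −0.55.

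**Figure D4:**
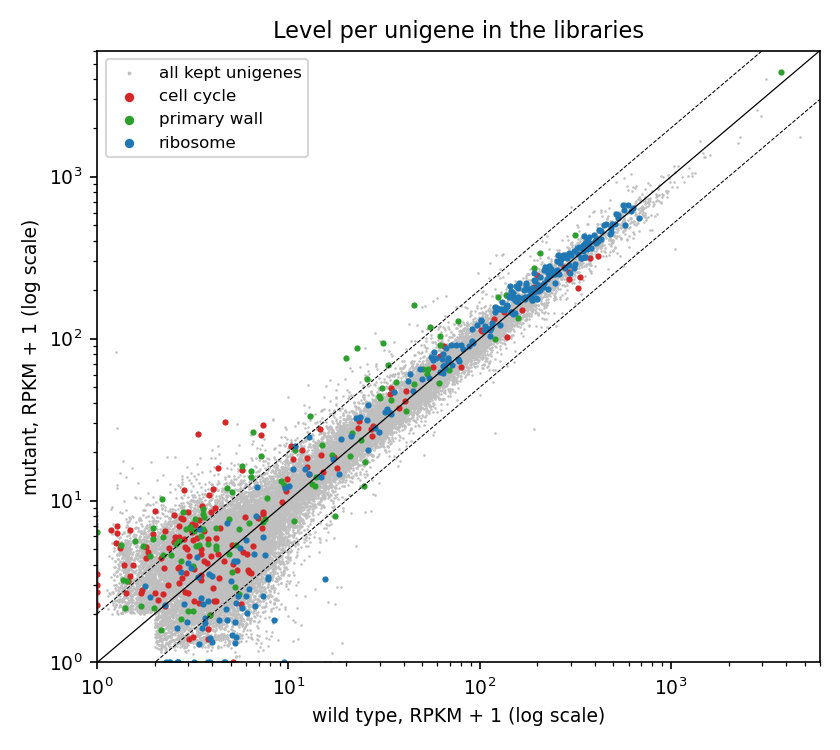
RPKM + 1 of each kept unigene in the wild-type (x) and mutant (y) library on log axes, with equality as a solid line, 2-fold as dashed lines, and cell cycle, primary wall and ribosome unigenes in colour. Primary wall and cell cycle unigenes lie mostly above the line (medians 0.57 and 0.37).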

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

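Restrictions by number block, reads, length, fungal hit and longest unigene were chosen after the data were seen. No paired analysis was possible because each group holds 1 library. The counts of unigenes at least 2-fold higher and lower (2948 and 1818) became 4579 and 3165 with a pseudocount of 0.1, 280 and 92 with 5, 1328 and 597 with a minimum RPKM of 5, and 249 and 138 at 4-fold. They became 332 and 99 in the first 2 number blocks, 306 and 85 with at least 100 reads, and 716 and 374 with at least 500 bases. A counting interval excluding 1 left 2138 and 1169. A larger pseudocount by construction shrinks ratios of sparsely read unigenes, and the restrictions leave fewer of them. Centring (2712 and 2032), trimmed-mean scaling (2803 and 1948), no minimum (2948 and 1818, as 2-fold already requires an RPKM of 1) and leaving out fungal hits (2916 and 1751) stayed within 1.5 times.

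Of 310 alternative list medians, 297 stayed within the 95% interval of the main median and 21 turned sign, 18 of them inside that interval, in lists with medians near 0. Floral repressors became 0.32 without a minimum and 0.52 with the longest unigene per entry (4 unigenes). Their median went the other way to −0.60 in the first 2 blocks and with a minimum RPKM of 5 (3 unigenes each). It became −0.46 with at least 500 bases (5 unigenes) and −0.10 with at least 100 reads (4 unigenes). Phloem became 0.51 with at least 100 reads. The ribosome median of 0.07 became 0.12 with a minimum RPKM of 5, 0.023 after centring, 0.13 in the first 2 blocks, with at least 100 reads or without fungal hits, and 0.12 with at least 500 bases. The cell cycle median became 0.19 in the first 2 blocks and 0.15 with at least 100 reads, primary wall 0.42 with a pseudocount of 5, autonomous and chromatin −0.029 after centring, and auxin −0.084 with the longest unigene per entry. The terpene median turned positive with at least 100 reads (2.98, 1 unigene) and with the longest unigene per entry (0.19, 3 unigenes), which leave too few members for a direction. Inside their intervals, other list medians also moved by over 1.5 times, and not all of them are given here. With a pseudocount of 5, floral promoters became 0.18, floral organ identity 0.37, cuticle 0.30, secondary wall 0.23, cell cycle 0.24, terpene −0.45 and disease resistance −0.061. In the first 2 blocks, cuticle became 0.30, jasmonate 0.28, cytokinin −0.13, meristem −0.035, abscisic acid 0.028, photosynthesis −0.041 and terpene −0.31 (2 unigenes). With at least 500 bases, floral promoters became 0.20, secondary wall 0.59, cuticle 0.30, meristem −0.0044 and photosynthesis −0.035. With at least 100 reads, floral promoters became 0.090 (5 unigenes), floral organ identity 0.31 (2 unigenes), photoperiod −0.19 and disease resistance −0.047. With a minimum RPKM of 5, floral organ identity became 0.31, secondary wall 0.60 and abscisic acid 0.014. With the longest unigene per entry, floral promoters became 0.73, photosynthesis −0.040, disease resistance −0.052 and flavonoid −0.0059, and late embryogenesis became −0.16 without a minimum. Organ identity with the accidental matches kept became 0.28. The causes of these shifts were not tested. Of 344 values of named unigenes under alternatives, 74 moved and 0 turned sign. No sign could turn, since a pseudocount keeps the sign. The offsets of centring (0.048) and trimmed-mean scaling (0.032) were smaller than every named log2 ratio in size. Low read counts limit most of the folds, and differences between trees cannot be judged.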

Other observations

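The survey of protein families, the number blocks and the tests of single-library assembly, of low read counts for the number blocks, of fungal RNA and of bud stage were chosen after the results they concern had been seen.

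Grouping unigenes by protein name gave 325 families with at least 10 kept members. Of these, 23 had a median in the top 0.5% of random lists matched on level and number block. Chance gives 1.62 per side if the members of a family are independent. Pieces of 1 transcript and related copies can share their direction, so the excess over 1.62 cannot be taken at face value. It also describes only 1 library per group. Peroxidases, which act on wall phenolics, had a median log2 ratio of 0.61 over 28 unigenes, with 8 at least 2-fold higher and 0 lower in the mutant library. Subtilisin-like proteases (33 unigenes, 0.55), nepenthesin-type aspartic proteinases (17, 0.63), thaumatin-like proteins (15, 0.76) and LOB domain proteins, transcription factors of organ boundaries (18, 0.49), were also high. The 18 unigenes named anthranilate N-benzoyltransferase had a median of 0.72, and 9 were 2-fold higher.

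In the bottom 0.5% lay 10 families. Pentatricopeptide repeat proteins, which process organelle RNA, had a median of −0.17 over 880 unigenes, with 53 higher and 87 lower. FtsH proteases of plastids and mitochondria (24 unigenes) had −0.20, and BEL1-like homeodomain proteins (13), partners of the KNOX meristem regulators, also had −0.20. ABC transporters of the C family (41) had −0.30. At most 2 reads in the mutant library against at least 40 in the wild type were found for 14 unigenes, and the converse for 9. The former include an APL-type MYB factor (0 against 115 reads), a neutral ceramidase (2 against 115) and DNA ligase 1 (0 against 44), named after their values were seen.

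Unigenes past 2-fold lay mainly in the later number blocks, with 86.7% of the higher ones in block 3 and 93.1% of the lower ones in block 4. Low read counts as the whole cause were argued against, since among unigenes with at least 100 reads the share past 2-fold in blocks 3 and 4 was 5.42 times that in blocks 1 and 2. Diverged copies of a gene split between unigenes were examined by shuffling the directions. Of the 847 higher unigenes of blocks 3 and 4 with a Swiss-Prot entry, 17.6% shared it with a lower one there. This was below the median of 22.3% over 2000 shuffles. Pieces of 1 transcript can share both entry and direction, could not be joined before shuffling, and would lower the observed share. The shuffles therefore cannot exclude split copies. A hypothesis is that block 3 was assembled mainly from mutant reads and block 4 mainly from wild-type reads, but the difference of 0.46 between their medians at 100 reads or more restates the pattern and does not test it. The assembly is not given in the sources used here, so unigenes assembled mainly from one library cannot be told apart from a difference between the genotypes.

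Ribosomal protein unigenes with a fungal best hit were lower in the mutant library. The number block as the whole cause was argued against. Within block 4, the 41 fungal hits had a median of −1.26 and the 23 ribosomal plant hits 0.08, a difference of −1.34. These groups were not matched on read depth, and the fungal hits held only 140 reads in the mutant library against 503. Over all 1991 plant hits of block 4 the median was −0.56, so −1.34 overstates the distance to the block at large. How far read depth contributes was not tested. RNA of a fungus in the wild-type buds is a hypothesis that the median of −1.20 over the 50 fungal hits raised and therefore does not test. Other unigenes with a filamentous fungal hit gave a median of −0.012, above the bound set in advance against fungal transcripts, but that bound was judged ill chosen after the value was seen, since 66 of these 106 lie in blocks 1 and 2 (median 0.03), where such a hit need not come from a fungus, and the 22 in block 4 had −1.42 against −0.56 for plant hits. Fungal transcripts beyond the ribosomal ones therefore cannot be told apart from plant ones here, and with 1 wild-type library a chance infection and a genotype difference are both open.

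Cell cycle unigenes were higher in the mutant library. The number block as the whole cause was argued against, since the list median lay at percentile 99.99 of random lists matched on level and block. Low read counts as the whole cause were also argued against. The 62 members with at least 100 reads had a median of 0.15 at percentile 99.64, with 10 at least 2-fold higher and 0 lower. Over all 156 members the median was 0.37, with 49 higher and 6 lower, so the difference was smaller without the sparsely read members. How far low read counts contribute to the larger value was not tested. The stage or make-up of the buds taken rather than genotype cannot be told apart from the mutation, with 1 library per genotype. A hypothesis that the mutant buds may have held more dividing and expanding tissue needs further libraries of each genotype, staged by dissection.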
